A study of Homo sapiens with 6 samples.

How the data were processed

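The series holds 6 RNA-seq libraries of poly(A) RNA from HCT116 cells, 3 treated with DMSO and 3 with 100 nM cortistatin A (CA) for 3 h. Per the labels' protocols, 15 cm dishes were plated in triplicate, grown to about 80% confluency and harvested in Trizol after washing, and libraries followed Illumina's standard protocol. The library kit, the read length and whether strand was kept are not given in the sources used here. Each sample's group came from its treatment label and title. One free-text field names DMSO for all 6 samples, and one field gives a blood disorder as the cell type, neither of which was used.

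The authors deposited 2 tables with 1 row per gene symbol. One holds whole-number counts for 23669 symbols, deposited by the authors without normalization, and 18138 of these have a count in any library. The other holds deposited CPM values (counts per 1000000 counts of a library) for exactly those 18138 genes. Each of its values equalled the count plus 0.5, divided by the library total plus 1 and scaled to CPM, within a relative difference of 3.27e-08, which is the linear form of what voom computes before its log2. TopHat, SAMtools 0.1.16, HTSeq 0.6.1, DESeq, limma and the build hg19 are named, with no role or order, per the submitters' processing notes. The gene annotation is not given in the sources used here. No coordinates are printed, because the reference at hand was another build (GRCh38, GENCODE 29). It served only for gene names, order, transcript GC content and length, and exon overlap. Of the 23669 symbols, 20952 matched by the same symbol, 1287 through an older symbol and 1430 not at all, and 96.7% of the genes tested had a GC content.

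Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM factors, filterByExpr with a minimum count of 10, and the quasi-likelihood test with group as the only term. P-values were two-sided and adjusted by Benjamini and Hochberg over the 13279 genes tested, with a threshold of 0.05 and no fold threshold. Log2 fold changes are CA minus DMSO. The SE beside each was computed from the spread of log2 CPM in the 3 libraries of each group (prior count 0.5), and the test used edgeR's moderated spread, so the SE and p do not convert into each other. CPM values are means with SD over n = 3 libraries. They were divided by each library's total over the genes tested, scaled by its TMM factor. CPM values of the cell type markers were divided by the library's whole total without that factor. Library totals ran from 21801415 to 36196417 counts. A gene at 1 CPM of the whole total therefore rests on 21.8 to 36.2 counts, depending on the library. The common dispersion was 0.00614, a biological coefficient of variation of 7.84%, and 0.00274 (5.24%) with the GC trend removed.

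Gene lists were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01), again with the correlation estimated, and with fry, each adjusted over 23 lists. For each list the number of members past the threshold over all genes tested stands beside the number adjusted over the list alone. Before the data were examined, the following were fixed: the tests, the 23 lists, the 4 lists of cell type markers, the alternatives other than those named below as later, and the rule for named genes. That rule took CDK8, CDK19, CCNC, MED12 and MED13, then the 12 genes with the largest change in each direction among those past the threshold with a mean of at least 50 normalized counts and groups that did not overlap. It went on with up to 4 members of each list past the threshold (or the 2 with the smallest p where none passed), IRF1, ETV6, CEBPA and IRF8, and the 3 most abundant markers of each cell type. Further members are named where they passed adjusted over the list alone, and these, with the genes named as uncertain, in the leave-one-out fits or listed at 0, were chosen after their values were seen. Some genes these rules select are not reported here.

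The alternatives were DESeq2 size factors and upper-quartile factors in edgeR, DESeq2 1.42.0, limma-voom, limma on the deposited CPM values in log2, no filter on low counts, a mean count of at least 10, the replicate number as a block, other thresholds, and leaving out each library. Chosen after seeing the data were a lowess trend (span 0.3) of each library on transcript GC content entered as offsets, that trend with the replicate block or with an estimated correlation, the 4 libraries other than DMSO 3 and CA 2, and thinning all libraries to 21801415 counts. Calls at equal depth rest on a single random thinning, and the medians and correlations given at equal depth on 20. The change of pseudocount planned for files without counts did not apply.

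The scripts were tested on simulated counts for CA against DMSO with 200 genes changed. Counts were drawn independently for each gene from the means and library sizes, with dispersions estimated after removing the GC trend. With the observed GC trends added (13201 genes), edgeR recovered 53.7% of genes changed by 0.4 on the log2 scale, 92.5% at 0.7 and 98.5% at 1, with 3 false calls among 166. With the GC trend removed it recovered 83.6%, 100% and 98.5%, with 14 false among 202. A planted list (13190 genes) was called with its direction under both correlations, and 0 of the other lists were. The added trend is the kind the correction removes, and simulated genes do not vary together. These rates are therefore favourable and do not give the share of false calls in the real libraries or lists. Genes sharing over 20% of their exonic bases with another gene in GENCODE 29 are reported as uncertain, since counting by strand is not stated. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.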

Results

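Poly(A) RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, after 3 h with 100 nM cortistatin A (CA) or with DMSO, its solvent. Cortistatin A is a steroidal alkaloid that inhibits CDK8 and CDK19, the kinases of the Mediator complex, which links transcription factors to RNA polymerase II. Dishes were plated in triplicate, so each group had 3 libraries. The labels do not say whether the dishes came from separate passages, and the p-values of single genes therefore measure the spread between dishes. Those of camera with the preset correlation and of Fisher's test compare genes with other genes and do not measure that spread. Counts assigned to genes totalled 35374876, 24665319 and 36196417 in DMSO 1, 2 and 3, and 21801415, 23574454 and 28097375 in CA 1, 2 and 3. The mean total was 32078871 for DMSO and 24491081 for CA, a difference that did not pass an exact permutation test (two-sided p = 0.2, where 3 against 3 cannot go below 0.1). No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 3.90, for CA 2 against CA 3.

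The comparison asked which transcripts changed within 3 h of inhibiting the Mediator kinases. Transcripts of the kinase module itself did not pass the test. CDK8 stood at 31.0 ± 0.74 CPM (TMM-scaled counts per 1000000 counts of a library, with SD, n = 3) in DMSO and 30.2 ± 0.59 in CA. CDK19 stood at 30.1 ± 2.35 and 29.1 ± 1.31. The log2 fold change (CA minus DMSO) was -0.04 ± 0.03 (SE) for CDK8, -0.05 ± 0.08 for CDK19, 0.17 ± 0.13 for their partner cyclin C (CCNC), -0.12 ± 0.09 for MED12 and -0.15 ± 0.10 for MED13, with adjusted p from 0.534 to 0.868 in edgeR's quasi-likelihood test. All 5 missed an unadjusted p of 0.05, and none passed in DESeq2 or limma-voom.

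Of 13279 genes tested, 44 passed an adjusted p of 0.05, 21 higher and 23 lower with CA. The changes were small. Of the 44, 20 differed by at least 1.5-fold and 4 by at least 2-fold, and the median absolute log2 fold change was 0.55. Those 4, EGR1, KLF2, JUN and CSRNP1, were all lower with CA, and the largest fold among the higher genes was 1.87, for ID3. In each of the 44 genes the 3 CA libraries lay on one side of the 3 DMSO libraries, which was also true of 18.6% of all genes tested, against 10% by chance. The count changed with the library left out. It was 25 without DMSO 1, 8 without DMSO 2 and 242 without DMSO 3, and 8, 7 and 6 without CA 1, CA 2 and CA 3. Leaving out a library also lowers power, which was not separated from the weight of single libraries. In all 6 of these fits 5 genes passed, EGR1, CDKN1A, CSRNP1, KRT80 and ID3. With the trend of each library on transcript GC content removed, a step chosen after seeing the data, 493 genes passed, 248 higher and 245 lower, among them all 44 with the same direction.

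The genes that fell most were led by EGR1 and KLF2. EGR1, an immediate early zinc finger factor, fell from 32.1 ± 0.74 to 7.39 ± 0.75 CPM, a 4.34-fold decrease (adjusted p = 6.18e-06 in edgeR). KLF2, a Krüppel-like factor, fell 2.74-fold (log2 -1.45 ± 0.27, adjusted p = 0.0163), and JUN, a subunit of AP-1, fell 2.09-fold (log2 -1.06 ± 0.25, adjusted p = 0.0420). CSRNP1, a nuclear protein gene first described as induced by AXIN1, fell 2.01-fold (log2 -1.01 ± 0.07). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, fell from 413 ± 19.0 to 221 ± 12.6 CPM, or 1.87-fold (adjusted p = 4.91e-04), and DDIT3, the stress-induced factor CHOP, fell 1.86-fold. The other genes in this group were LRP1, an endocytic receptor (log2 -0.88 ± 0.15), MIR22HG, the host transcript of a microRNA (-0.83 ± 0.11), SERTAD1 (-0.76 ± 0.11), MXD1, a MAX partner and MYC antagonist (-0.74 ± 0.08), RCOR2, a corepressor subunit (-0.68 ± 0.07), and DNAJB1, an HSP40 co-chaperone (-0.63 ± 0.07). JUN and MIR22HG missed the threshold in limma-voom on the same counts.

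The genes that rose most were led by ID3 and KRT80. ID3, an inhibitor of basic helix-loop-helix factors, rose from 52.0 ± 2.69 to 97.2 ± 8.70 CPM (log2 0.90 ± 0.09, adjusted p = 0.00203 in edgeR). KRT80, a keratin, rose 1.79-fold from 6.76 ± 0.14 to 12.1 ± 0.61 CPM (adjusted p = 0.00465). SLC16A6, a monocarboxylate transporter family member, had a log2 fold change of 0.66 ± 0.08, BHLHE40, a hypoxia-inducible basic helix-loop-helix repressor, 0.60 ± 0.09, and DHRS3, a retinaldehyde reductase, 0.60 ± 0.06. FGFBP1, a carrier of fibroblast growth factors, rose by 0.55 ± 0.08 and SH3RF1, a ubiquitin ligase and JNK scaffold, by 0.54 ± 0.02. Also in the group were HOXB8, a homeobox gene (0.50 ± 0.08), KLF5, an epithelial Krüppel-like factor (0.50 ± 0.07), MYEOV (0.48 ± 0.05) and ELF3, an epithelial ETS factor (0.48 ± 0.04). FGFBP1 missed the threshold in a single random thinning of the libraries to equal depth.

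**Figure D1:**
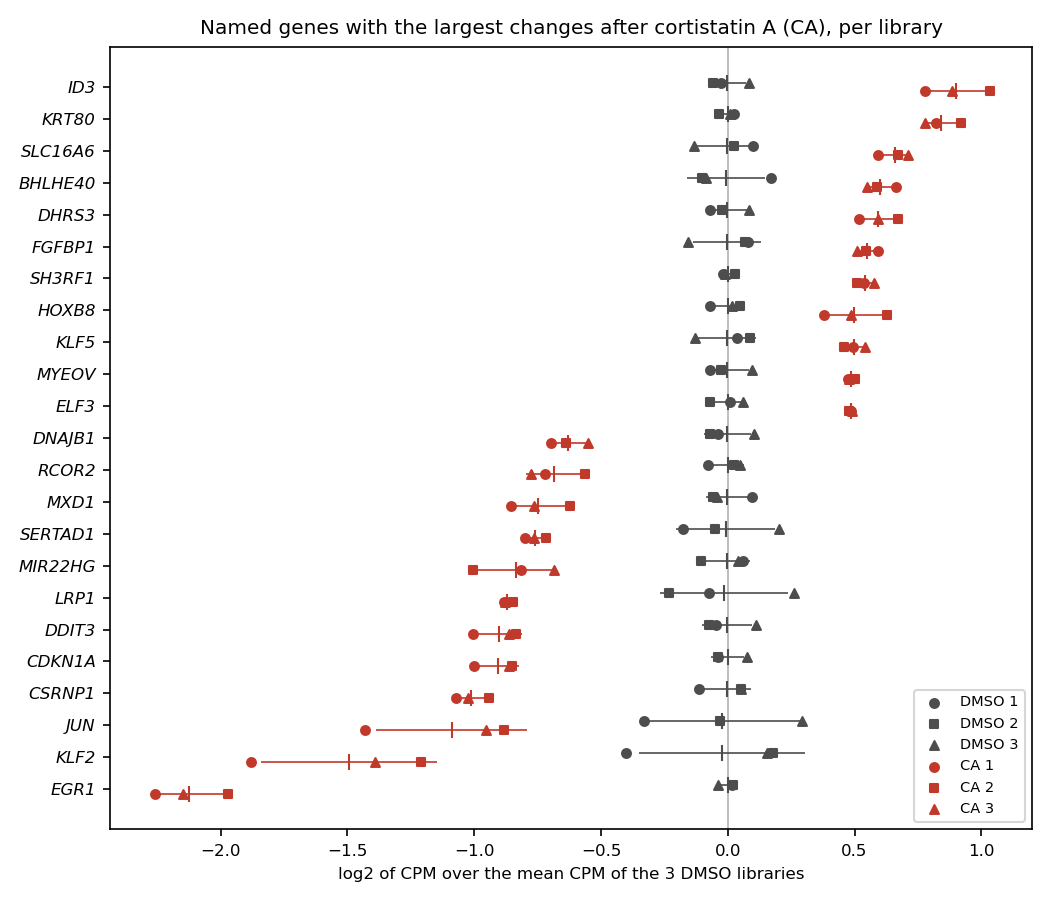
Log2 of the CPM of each library over the mean CPM of the 3 DMSO libraries, for the genes named above that rose or fell most. Points are libraries (grey, DMSO; red, CA; the symbol gives the replicate), the small vertical bars are group means and the horizontal lines 1 SD to each side (n = 3). In each gene shown the CA points lie to one side of the DMSO points, furthest for EGR1 (log2 fold change -2.12).

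Among 23 gene lists fixed before the data were examined, 11 passed camera with its preset inter-gene correlation of 0.01, 6 lower and 5 higher, and 1, the p53 targets, also passed with the correlation estimated from the data. The estimate was -0.016 for the p53 targets and 0.0153 for the SMAD targets. Their larger p-values under that setting therefore do not show that members varied together. Of 27 measured p53 targets, 26 had a negative fold change and the median was -0.16 on the log2 scale (adjusted p = 3.86e-11, and 0.0332 with an estimated correlation). CDKN1A was the 1 member past the threshold over all genes tested, and adjusted over the list alone 5 fell. They were CDKN1A, MDM2, which encodes the ubiquitin ligase of p53 (log2 -0.34 ± 0.11), PLK3 (-0.50 ± 0.13), DDB2 (-0.31 ± 0.06) and PHLDA3 (-0.37 ± 0.12).

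The immediate early genes were lower as a list, with a median log2 fold change of -0.25 over 24 measured members, of which 18 were negative (adjusted p = 3.86e-11 in camera, and 0.131 with an estimated correlation). EGR1, KLF2 and JUN fell, MYC rose and 20 members did not pass. Adjusted over the list alone, 9 fell and 4 rose. FOS (-0.53 ± 0.16), EGR2 (-1.24 ± 0.30) and ATF3 (-0.38 ± 0.05) were among those lower by that measure, and KLF4 (0.47 ± 0.12) and NR4A2 (0.30 ± 0.09) among those higher. IER3, listed with a mean of 0.333 counts, lies in a stretch of chromosome 6 where many genes were listed at 0.

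Heat shock genes were also lower (median -0.12 over 16 measured members, 13 negative, adjusted p = 2.09e-06, and 0.217 with an estimated correlation). DNAJB1 fell, and so did HSPA8, the constitutive HSC70 chaperone, from 3297 ± 145 to 2480 ± 107 CPM (log2 -0.41 ± 0.05), while 14 members did not pass. Adjusted over the list alone, 3 fell, the third being DNAJA1 (-0.23 ± 0.05). HSPA8 missed the threshold in limma on the deposited voom values, and HSPA1B, at -0.61 ± 0.30, shares reads with its near-identical copy HSPA1A and is uncertain. In the ATF4 and unfolded protein response list, DDIT3 and PPP1R15A (-0.40 ± 0.03), a phosphatase subunit that ends the translational block of stressed cells, fell and 19 of 21 measured members did not pass. Adjusted over the list alone, 4 fell and 2 rose, XBP1 (0.25 ± 0.07) and DNAJB9 (0.31 ± 0.07) being the ones that rose. That list's call (adjusted p = 0.0431) was lost with an estimated correlation (adjusted p = 0.629), with the GC trend removed (0.103) and with no filter on low counts (0.0633). It was also lost without DMSO 2 (0.106), DMSO 3 (0.543) or CA 1 (0.336), and without both DMSO 3 and CA 2 (0.239).

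No single member passed in the other 2 lists that were lower, in edgeR, DESeq2 or limma-voom. NF-kappaB targets had a median of -0.16 over 15 measured members, 13 of them negative (adjusted p = 0.0121, and 0.273 with an estimated correlation), with 2 members at an unadjusted p under 0.05 and none past the threshold adjusted over the list alone. TNF and LTB were listed at 0. The members with the smallest p were CXCL1, a chemokine near the detection limit (0.72 ± 0.03 CPM in DMSO, 0.41 ± 0.11 in CA), and TNFAIP2 (log2 -0.18 ± 0.07). The list lost its call without DMSO 3 (0.112) or CA 1 (0.0837), and with no filter on low counts (0.0533). Of 38 cytosolic ribosomal protein genes, 31 had a negative fold change, with a median of -0.08 (adjusted p = 0.00562, and 0.640 with an estimated correlation). RPL32 (-0.17 ± 0.07) was among the 2 at an unadjusted p under 0.05, and the call was lost without DMSO 3 (adjusted p = 0.618) and without both DMSO 3 and CA 2 (0.218).

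SMAD targets, genes that respond to TGF-beta and BMP signals, were the list with the highest median (0.24 over 14 measured members, 11 positive, adjusted p = 7.13e-07, and 0.0756 with an estimated correlation). ID3 rose and 13 members did not pass over all genes tested. Adjusted over the list alone, 8 rose and 1 fell. Those that rose included SMAD7, an inhibitor of TGF-beta receptors (0.74 ± 0.18), PMEPA1 (0.79 ± 0.19), ID1 (0.49 ± 0.26) and BAMBI (0.37 ± 0.10).

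Genes of cholesterol synthesis regulated by SREBP2 were higher as a list (median 0.07 over 25 measured members, 18 positive, adjusted p = 4.72e-04, and 0.181 with an estimated correlation). None passed over all genes tested in edgeR, where 9 had an unadjusted p under 0.05, and 4 passed in DESeq2, with SQLE, squalene epoxidase, at 105 ± 12.6 CPM in DMSO and 142 ± 6.23 in CA (log2 0.43 ± 0.11, adjusted p = 0.0811) and MSMO1 at 0.53 ± 0.17 (adjusted p = 0.108). Adjusted over the list alone, 5 rose, among them SQLE, MSMO1, INSIG1 and SC5DL. HIF1 and hypoxia targets were higher (median 0.13 over 23 measured members, 19 positive, adjusted p = 5.39e-04, and 0.217 with an estimated correlation). BHLHE40 rose, 22 members did not pass, and adjusted over the list alone 2 rose, the other being ADM, adrenomedullin (0.45 ± 0.12).

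MYC itself, the proto-oncogene encoding a growth-promoting transcription factor, rose from 365 ± 15.8 to 473 ± 22.1 CPM (log2 0.37 ± 0.05, adjusted p = 0.0420 in edgeR). That call was lost with upper-quartile factors and in a single random thinning to equal depth. MYC targets had a median of 0.07 over 24 measured members, 20 of them positive (adjusted p = 0.0121, and 0.249 with an estimated correlation), with 3 members at an unadjusted p under 0.05 and none past the threshold in edgeR or DESeq2, or adjusted over the list alone. TFAP4 (0.22 ± 0.03) and PPAN (0.61 ± 0.30) had the smallest p. PPAN shares 83.2% of its exonic bases with a readthrough transcript and is uncertain, and the list lost its call without DMSO 1 (0.107). Notch targets were higher (median 0.08 over 10 measured members, 6 positive, adjusted p = 0.0191, and 0.273 with an estimated correlation). MYC, a member of this list too, was the 1 past the threshold and 9 did not pass, and adjusted over the list alone 3 rose, with HES1 (0.46 ± 0.07) and JAG1 (0.29 ± 0.04) beside it. The Notch call was lost without DMSO 1 (0.137), DMSO 2 (0.0555), CA 2 (0.0926) or CA 3 (0.0519), and with no filter on low counts (0.0900).

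**Figure D2:**
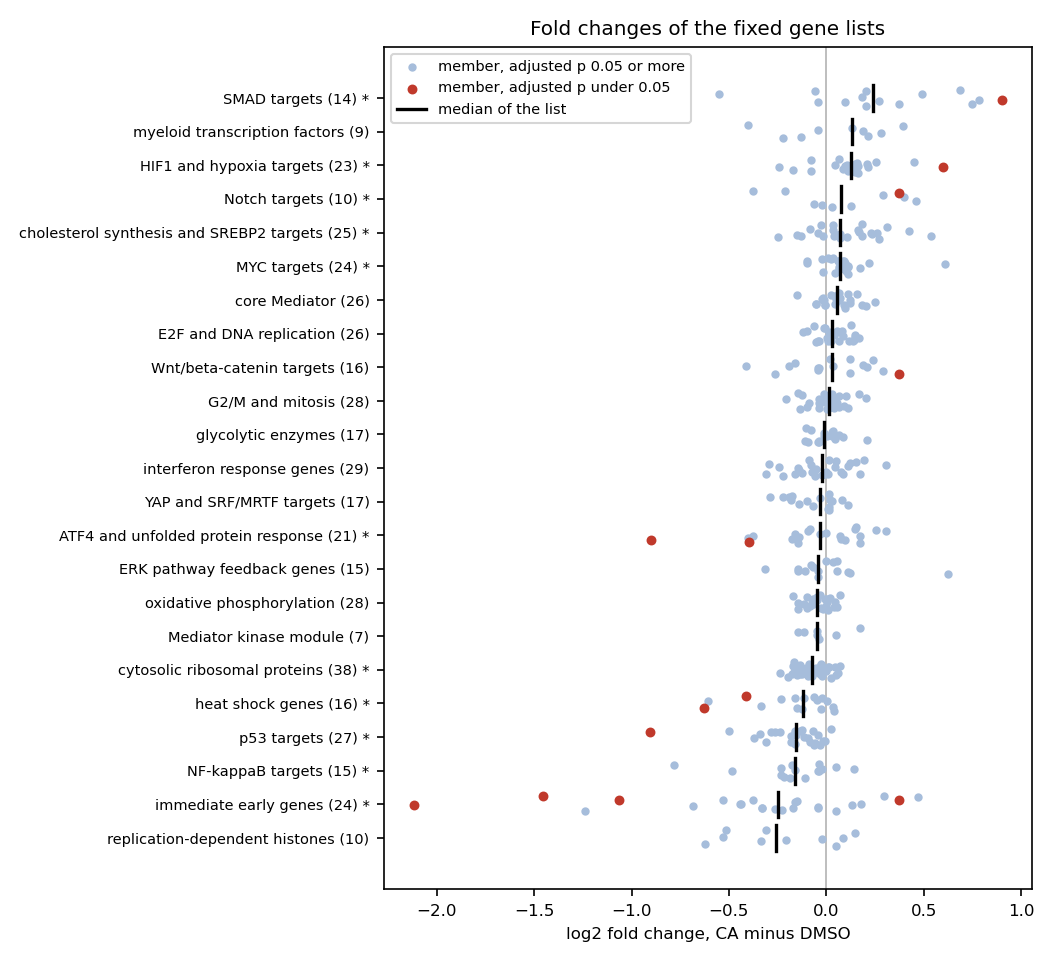
Log2 fold changes (CA minus DMSO) of the measured members of the 23 fixed gene lists, with the number of measured members in brackets and an asterisk where the list passed camera with the preset correlation. Each point is a gene, red where it passed an adjusted p of 0.05, and the black bar is the median of the list. The p53 targets lie almost all to the left of 0 (26 of 27) and the SMAD targets mostly to the right (11 of 14).

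The other 12 lists did not pass. In 11 of them no member passed over all genes tested in edgeR, and the count in DESeq2 and limma-voom was 0 as well except for 1 ERK feedback gene in DESeq2. Wnt/beta-catenin targets, of interest because HCT116 carries an activated beta-catenin, had a median of 0.03 over 16 measured members (adjusted p = 0.0994). MYC rose and 15 did not pass, and adjusted over the list alone 3 rose and 2 fell, AXIN2 (-0.26 ± 0.04) and EPHB3 (-0.41 ± 0.12) being lower and RNF43 (0.19 ± 0.04) and ZNRF3 (0.24 ± 0.04) higher. This list passed with the GC trend removed (adjusted p = 0.0303, and 0.193 with an estimated correlation), without DMSO 3 (0.0241) and without both DMSO 3 and CA 2 (0.0264). With all libraries and an estimated correlation it had an adjusted p of 0.273. The Mediator kinase module had a median of -0.05 over 7 measured members (adjusted p = 0.750) and core Mediator one of 0.05 over 26 (adjusted p = 0.0994, 3 members at an unadjusted p under 0.05), where MED10 (0.18 ± 0.03) and MED28 (0.25 ± 0.11) had the smallest p. Core Mediator passed without both DMSO 3 and CA 2 (0.0465), and with all libraries and an estimated correlation its adjusted p was 0.273. MED28 shares 32.4% of its exonic bases with a gene on the other strand and is uncertain.

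Of the proliferation lists, E2F and DNA replication genes had a median of 0.03 over 26 measured members (adjusted p = 0.129, 3 members at an unadjusted p under 0.05), with E2F8 at 0.17 ± 0.05 and MCM10 at 0.15 ± 0.05. G2/M genes had a median of 0.01 and a positive mean while camera gave a negative direction (adjusted p = 0.917, 28 members, 1 at an unadjusted p under 0.05), with KIF20A at -0.21 ± 0.07 and CCNB1 at -0.13 ± 0.05. Replication-dependent histones had a median of -0.26 over 10 measured members (adjusted p = 0.0863), and 1, HIST2H2BE (-0.53 ± 0.09), passed adjusted over the list alone, with HIST1H2AC at -0.52 ± 0.30. That median was the furthest from 0 of the 23 lists. The list passed without DMSO 1 (0.00551) or CA 3 (0.00775) and with the replicate number as a block (0.0409), and with all libraries and an estimated correlation its adjusted p was 0.629. Of the metabolic lists, oxidative phosphorylation had a median of -0.05 over 28 (adjusted p = 0.0994, 0.0123 without DMSO 1, and 0.651 with an estimated correlation), with NDUFA1 at -0.17 ± 0.07 and UQCRB at -0.15 ± 0.06, and NDUFA1 shares 44.5% of its exonic bases with a gene on the other strand. Glycolytic enzymes had a median of -0.01 over 17 (adjusted p = 0.917), with ALDOC at 0.21 ± 0.10 and HK1 at -0.11 ± 0.05.

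Of the signalling lists, ERK feedback genes had a median of -0.04 and a mean of 0.00199 over 15 measured members, with a negative direction in camera (adjusted p = 0.863) and 3 members at an unadjusted p under 0.05. SPRY1, a feedback inhibitor of receptor tyrosine kinases, rose adjusted over the list alone (0.62 ± 0.11), and EPHA2 stood at -0.32 ± 0.15. YAP and SRF/MRTF targets had a median of -0.03 over 17 (adjusted p = 0.118, 0.010 without DMSO 1, and 0.651 with an estimated correlation), with AJUBA at -0.29 ± 0.08 and AMOTL2 at -0.18 ± 0.08. Interferon response genes had a median of -0.02 over 29 measured members (adjusted p = 0.729), with 3 members at an unadjusted p under 0.05 and none past the threshold adjusted over the list alone. IRF1 stood at -0.22 ± 0.08 (adjusted p = 0.340) and OASL at -0.31 ± 0.09, and PSMB8, PSMB9 and TAP1 were listed at 0. Myeloid transcription factors, chosen because CA acts on such genes in leukaemia cells, had a median of 0.13 over 9 measured members (adjusted p = 0.917), 4 of them at an unadjusted p under 0.05. GFI1 fell adjusted over the list alone (-0.40 ± 0.03), RUNX1 stood at 0.19 ± 0.07, ETV6 at 0.13 ± 0.11 (adjusted p = 0.654) and CEBPA at -0.04 ± 0.14 (adjusted p = 0.927). CEBPA shares 43.4% of its exonic bases with other-strand transcripts and is uncertain, and IRF8, with 1 count in DMSO 3 and 0 in the other 5 libraries, was not tested.

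The libraries carried the transcripts of an epithelial cell. Keratins KRT8, KRT18 and KRT19 stood at 2704 ± 334, 1361 ± 91.0 and 783 ± 92.5 CPM in DMSO. The 18 colon epithelial markers totalled 5682 ± 528 CPM in DMSO and 5788 ± 137 in CA, mostly from these keratins. Of the 18, 11 had enough counts to be tested, CDX2 and KRT20 (2.45 ± 0.15 CPM in DMSO) among them. Of those not tested, CEACAM5 was the highest in DMSO (0.21 ± 0.06 CPM), and CDX1 and CEACAM6 were listed at 0. The total therefore does not show that colon markers were broadly present. The 14 megakaryocyte and platelet markers totalled 32.8 ± 2.75 and 31.9 ± 0.39 CPM, of which THBS1, a gene also expressed outside platelets, gave 29.7 ± 3.01 in DMSO, ahead of NFE2 (0.92 ± 0.19) and ITGA2B (0.70 ± 0.07). Leukocyte and progenitor markers totalled 24.9 ± 2.07 and 24.2 ± 2.0 CPM, mostly from VAV1 (18.9 ± 1.48 in DMSO, against 3.01 ± 0.88 for CORO1A and 1.36 ± 0.19 for LYZ), and fibroblast markers 17.03 ± 0.87 and 14.6 ± 1.03, led by COL1A1 (10.3 ± 0.75), VIM (6.36 ± 1.62) and PDGFRB (0.29 ± 0.05). Of the 23 markers tested in edgeR, 6 had an unadjusted p under 0.05 and none passed between the groups, in DESeq2 or limma-voom either, while with the GC trend removed VDR, a colon epithelial marker, was lower (log2 -0.27, adjusted p = 0.0274).

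Within the groups, libraries differed along transcript GC content. DMSO 3 lay higher for GC-rich transcripts, with a correlation across genes of 0.71 between its deviation from the DMSO mean and GC content, and CA 2 likewise (0.58), while DMSO 1 (-0.50), DMSO 2 (-0.51) and CA 1 (-0.48) lay the other way and CA 3 showed little trend (-0.03). Genes are not independent replicates in these correlations. The deviations of a gene sum to 0 within each group, so the correlations of a group's libraries are not separate observations. Between the groups the fold change correlated with GC content at -0.13 across genes. Of the called genes, 3 share over 20% of their exonic bases with other genes and are uncertain, CD3EAP (50.2%), PLAU (28.7%) and ATF5 (24.7%). With the trend removed, the members of the fixed lists past the threshold were, as higher and lower, 2 and 5 of the immediate early genes, 0 and 7 of the p53 targets, 0 and 3 of the heat shock genes, 2 and 4 of the ATF4 list, 3 and 1 of the SMAD targets, 7 and 0 of the cholesterol synthesis genes, 2 and 1 of the hypoxia targets, 1 and 0 of the MYC targets, 3 and 0 of the Notch targets, 4 and 0 of the Wnt targets, 1 and 1 of the ERK feedback genes, 0 and 1 of the myeloid factors, and 0 in the other lists.

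**Figure D3:**
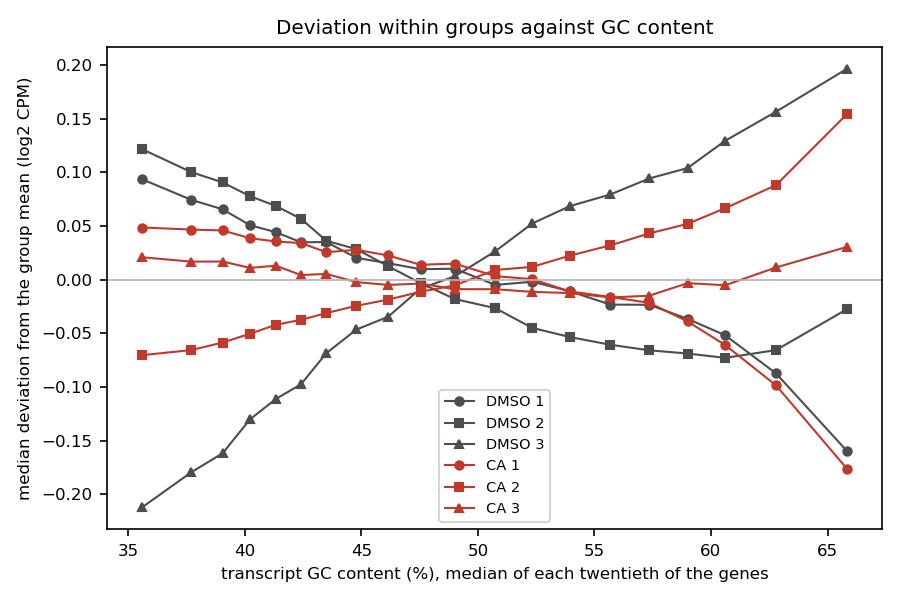
Median deviation of each library from its group mean (log2 CPM) against transcript GC content (percent), in bins that each hold a twentieth of the genes with a mean count of at least 50. Lines are libraries (grey, DMSO; red, CA; the symbol gives the replicate). DMSO 3 and CA 2 rise with GC content, with correlations across genes of 0.71 and 0.58.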

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

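The GC-corrected fits, the fit on 4 libraries and the thinned counts were chosen after the data were seen, and the other alternatives before. The 44 called genes kept their direction in all of the alternatives listed here, leave-one-out fits included. Their groups did not overlap and the fits use the same counts, so this was nearly fixed in advance and adds no support. The number past the threshold depended on the fit. It stayed between 37 and 44 with DESeq2 size factors, upper-quartile factors, limma-voom, limma on the deposited values, a mean count of at least 10 and equal depth. It was 187 (103 higher, 84 lower) in DESeq2, 100 (55 and 45) with no filter on low counts, where more genes were tested, 136 (74 and 62) in the 4 libraries other than DMSO 3 and CA 2, and 493 (248 and 245) GC-corrected. At an adjusted p under 0.01 it was 9 (4 and 5), under 0.10 it was 127 (63 and 64), and with a fold of at least 1.5 it was 20 (6 and 14). Of the 44, all were among the DESeq2 and GC-corrected calls, and 43 among those of the 4 libraries. Leaving out 1 library gave 6 to 242 calls, 2 to 129 higher and 4 to 113 lower. The rise to 242 came without DMSO 3, and without CA 3 there were 6. For the DESeq2 count the cause was not tested.

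With the replicate number as a block, 77 genes passed (41 higher, 36 lower), 41 of them shared with the 44, and 933 (463 and 470) with the GC trend also removed. Deviations of same-numbered libraries correlated at 0.55, -0.26 and 0.05 across genes, and at 0.38, -0.01 and 0.12 with the GC trend removed. Neither set has all 3 over 0.1, a level for pairing that was set after the data were seen. The fit as reported has no block because it was planned so, as no label pairs the replicate numbers. A shared effect in some of the numbers stays open, and the cause of the change in calls was not tested. Under the block the Notch (adjusted p = 0.0621) and ATF4 lists (0.0707) were no longer called and the replication-dependent histones were (0.0409, and 0.629 with all libraries, no block and an estimated correlation). Of the 11 lists called with the preset correlation, 1 passed with an estimated correlation, 1 GC-corrected with an estimated correlation, and 4 in fry (p53 targets, SMAD targets, cholesterol synthesis and immediate early genes), which does not compare a list with other genes.

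Results that turned direction were uncalled in the fit as reported and in each fit where they turned. For glycolytic enzymes the adjusted p was 0.947 with no filter, 0.715 GC-corrected, 0.871 GC-corrected with an estimated correlation, 0.0867 in the 4 libraries, and 0.0971 to 0.996 leaving out 1 library. For G2/M genes it was 0.947 with no filter, 0.951 with the block and 0.336 to 0.936 leaving out 1 library. Leaving out 1 library gave 0.336 to 0.996 for the Mediator kinase module, 0.534 to 0.996 for ERK feedback genes, 0.010 to 0.944 for YAP and SRF/MRTF targets, 0.0123 to 0.867 for oxidative phosphorylation and 0.492 to 0.980 for myeloid transcription factors. The log2 fold change of CDK19 ran from -0.11 to 0.00286 and that of CEBPA from -0.16 to 0.10, with 0.069 in the 4 libraries. The cause of these turns was not tested. Equal depth, in a single random thinning, left 38 calls, 37 of them among the 44, and what the lower depth of the CA libraries cost in calls was not tested. For genes with hardly any counts, such as IRF8, no difference was detectable at this depth.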

Other observations

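The genes in the first paragraph were chosen after their values were seen, from the fit with the GC trend removed. Of 149 families with at least 10 tested members, the KLF genes were the 1 with an adjusted p under 0.05 in Fisher's exact test among the genes that rose (4 of 14, adjusted p = 0.0306 over 298 tests). KLF3 (log2 0.28), KLF4 (0.49), KLF5 (0.50) and KLF11 (0.51) rose while KLF2 fell (-1.47). Without the GC correction KLF5 and KLF2 alone of these passed, with adjusted p = 0.247 for KLF3, 0.105 for KLF4 and 0.120 for KLF11, and the families were not tested in that fit. Among small nucleolar RNA host genes, SNHG1 (-0.32), SNHG5 (-0.20) and SNHG12 (-0.32) fell, 3 of 13 tested, which did not hold after correction over the families (adjusted p = 0.231). PPM1D, a phosphatase gene that p53 induces, fell as well (-0.36).

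Chosen after their results were seen were the tests of GC content, of the replicate numbers, of handling time and of alternate copies in 6p21 alone, and the count of 6p21 genes with at least 10 counts. The predictions of the other tests were set down before. The first pattern was that, of 9 called genes in the immediate early, p53, heat shock and ATF4 lists, 8 fell (EGR1, KLF2, JUN, CDKN1A, DDIT3, PPP1R15A, DNAJB1 and HSPA8) and MYC rose, with a median log2 fold change of -0.90 over all 9. Removing the GC trend left it at -0.89, which argues against that trend as the whole cause. Thinning to equal depth also left it at -0.89 (SD 0.0194 over 20 thinnings). Thinning keeps each gene's expected share of its library, so this value cannot decide whether depth played a part. Immediate early genes such as EGR1 and JUN also respond within minutes to a change of medium or to washing. How fast the called genes of the other lists respond to handling was not tested. As 0 labels record handling per dish, a difference in handling cannot be told apart from an effect of CA on the genes of this pattern. Inhibition of the Mediator kinases, the difference the design names, stays open as untested, and CA given to cells whose CDK8 and CDK19 do not bind it, handled alike, would decide between the 2. Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 44 genes, and the highest other called 0. With the GC trend removed the real split called 493 and the highest other 0, again 1 split of 10, and 10 splits are too few for a share under 0.05.

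A second pattern was an axis along which the libraries differed within groups, with DMSO 3 and CA 2 at one end. A trend on GC content between libraries is a candidate explanation, since the deviations of both correlated with transcript GC content across genes (the smaller at 0.58), and removing the trend lowered the common dispersion from 0.00614 to 0.00274. It does not account for the whole axis, as after the correction the deviations of DMSO 3 and CA 2 still correlated at 0.25 and those of DMSO 1 and CA 1 at 0.38 (0.55 before). Thinning to equal depth left the deviations of DMSO 3 and CA 2 correlated at 0.51 (SD 0.00410 over 20 thinnings, 0.54 before). Because thinning keeps each gene's expected share of its library, this value cannot decide on depth. DMSO 1 and DMSO 3, at 35374876 and 36196417 counts, lay at opposite ends, with correlations of -0.50 and 0.71 with GC content. That argues against depth alone as the source of the axis. A day or dish shared by replicate number is argued against as the source of this axis, whose ends DMSO 3 and CA 2 carry different numbers, the lowest correlation of same-numbered libraries being -0.26. After the GC correction the same-numbered libraries correlated at 0.38, -0.01 and 0.12, so a smaller shared effect, as between DMSO 1 and CA 1, stays open. What set the GC trend, such as amplification or fragmentation, was not tested.

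The last pattern lay in the stretch of chromosome 6 from TRIM27 to PHF1, called 6p21 here for short. Of its 161 protein-coding genes, 106 (65.8%) were listed at 0 in all 6 libraries, against 126 of 791 (15.9%) on the rest of the chromosome. They included RPS18, a ribosomal protein gene every cell uses, while the lowest mean of the ribosomal protein genes in the fixed list was 8343 counts. Reads discarded because hg19 also holds alternate copies of regions such as 6p21 and 17q21 are argued against by the prediction set down for that, since 0 of 7 genes of the 17q21 haplotype were listed at 0, although 3 of the 7 had means under 10 counts (in 6p21, 12 of 17 housekeeping genes were at 0 and 14 under 10). Loss or silence of the region in this line had predicted those 17q21 counts, yet it is argued against for the stretch as a whole by 18 genes with a mean of at least 10 counts in it, HLA-B (429), HLA-C (634) and MICA (448) among them, and for parts of it was not tested. Copies in 6p21 alone, if more alike than those of 17q21, cannot be told apart from other causes, because 0 files of reads were at hand to align without them. With RPS18 at 0, a listed 0 (IER3, HSPA1A, TNF, LTB, PSMB8, PSMB9 and TAP1 in the lists were at or near it) does not show a silent gene.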
